A study of Mus musculus with 8 samples.

How the data were processed

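CD45-positive cells were sorted from liver, lung, peritoneal cavity and spleen of wild-type B6 mice aged 3 or 17 months and sequenced as 5′ droplet libraries, with 3 mice pooled per library and 1 library per tissue and age. The deposited files of each library held raw UMI counts per gene and cell barcode for 31053 genes, and the authors named Cell Ranger, Seurat and the mouse build mm10 in their processing notes. The version in the file headers was Cell Ranger 3.0.2. Every deposited barcode had at least 500 UMIs, so the matrices held called cells. Gene identifiers were matched to GENCODE release M21 (GRCm38), which held 30766 of the 31053. Only the gene expression counts were used, and the receptor libraries made from the same cells were not analysed here.

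Total UMIs per library ran from 6367295 in the young liver to 35979742 in the young peritoneal cavity, and median UMIs per barcode from 2566 in the aged spleen to 5399 in the young peritoneal cavity. Cells with at least 200 genes and at most 10% mitochondrial UMIs were kept. Doublets were scored with Scrublet as implemented in scanpy, and the highest-scoring cells were removed, 0.8% of a library per 1000 of its cells, which came to 1.19% of the young liver and 8.50% of the aged spleen. This left 40346 of 47754 cells. The intervals printed show the precision that these depths gave.

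Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen with the library as batch key. Immunoglobulin and T cell receptor segments, ribosomal protein, mitochondrial and sex-linked genes were left out of this choice. On 40 principal components, 15 neighbours and Leiden resolution 1.5 with 4 iterations and a fixed seed, all 8 libraries were clustered together without batch correction. Clusters in which at least 60% of cells had a Cd3e, Cd3d or Cd3g UMI were pooled and clustered a further time in the same way, which gave 68 clusters, 28 of them T cell clusters.

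Clusters were named by a fixed marker table. For T cells, a CD8 or CD4 cluster needed at least 25% of cells with UMIs of that co-receptor alone, and at least 3 times the share with the other alone. Other clusters took the class with the highest mean scaled marker level, and classes within 0.9 of the best were ranked by markers among the 10 leading genes. A name needed 3 markers detected in at least 20% of the cluster's cells, and no other class with more markers among the leading genes. The 16 clusters that failed held 3467 cells (8.59%) and stayed unnamed.

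Shares of cells are given with exact Clopper-Pearson 95% intervals. For gene levels, UMIs were summed over the cells of a class in each library and scaled to the summed UMIs as CPM, and 0.5 counts were added to each sum for the log2 ratio. Its interval is the exact conditional binomial interval of the ratio of the sums. A class was compared in a tissue when it had at least 50 cells in both libraries. Cells were not treated as replicates, so no p-value or count of significant genes is given. A count of 0 is given a floor of 3 counts.

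Genes were named by a rule on size. Eligible genes had at least 50 summed UMIs in each compared tissue. The first part took up to 10 genes per direction whose interval bound nearest 0 was beyond 1.5-fold in every compared tissue. The second part took the 3 genes per direction and tissue with the largest bound, at least 2-fold, and the third part the members of fixed gene lists. For each list the median log2 ratio of members with at least 20 summed UMIs was set against 10000 random lists matched on mean expression. Marker table, lists, named-gene rule and the first set of alternatives were fixed before the data were examined.

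For shares of CD8 T-like cells with a UMI of Gzmk, Pdcd1 or Tox, each cell was thinned at random to 1000 UMIs, cells below that depth were left out, and B-like cells of the same library, treated alike, gave the background. V gene usage was counted in cells with UMIs of exactly 1 V gene. The effective number of V genes, the exponential of the Shannon entropy, was the mean of 100 draws down to the same number of cells per tissue. Xist gave 0 to 2 UMIs and the Y-linked Ddx3y 48.6 to 114 CPM in the libraries, so each library held male cells. The files hold no read positions, so the Nnt counts could not check the substrain.

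The procedure was tested on simulated data, Poisson counts drawn from real class sums with known folds set on some genes. Among spleen B-like cells, 80.8% of genes set 2-fold apart and 99.0% of genes set 4-fold apart were recovered, with 0% of unchanged genes. Among CD8 T-like cells the 2-fold and 4-fold values were 28.0% and 100% in liver and 59.2% and 96.9% in spleen, with 0.0339% and 0.0133% of unchanged genes. Intervals held the set ratio for 93.9% to 98.0% of genes. A gene counted as recovered when its interval bound nearest 0 was beyond 1.5-fold in the set direction. Both ages were drawn from the same pooled profile with counting error only, so few unchanged genes could pass. Differences between mice, library preparations, cell naming and free RNA were not simulated, so these values do not cover them.

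Alternatives changed the cell filter (at least 500 genes and at most 5% mitochondrial UMIs, or all barcodes), doublet removal, Leiden resolution (0.8 or 2.5) and variable genes (4000). They also clustered each tissue on its own, replaced clusters by UMI gates on single cells, thinned to 500, 2000 or not at all, and changed scaling (size factors, totals without immunoglobulin, mitochondrial and ribosomal protein genes, or a mean over cells of counts per 10000). List alternatives required 1 or 100 summed UMIs or added 2 counts. Chosen after seeing the data were clustering from the second and the third random start, NK-led clusters counted as CD8, CD4 cells picked by UMIs, the macrophage cluster with the most cells in a tissue taken alone, and subtraction of the trend on GC content of the first 300 nt in 20 bins. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9 were used.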

Results

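The series profiled CD45-positive leukocytes of wild-type B6 mice by droplet 5′ single-cell RNA sequencing in liver, lung, peritoneal cavity and spleen at 3 months (young) and 17 months (aged). Each of the 8 libraries pooled 3 mice, so every group had 1 library and no replicate. The libraries held 1513 to 10618 barcodes and 6367295 to 35979742 UMIs, and 40346 of 47754 cells were kept. All intervals are exact 95% intervals for counting error only, and none covers differences between mice or library preparations. A count of 0 is given the upper limit of 3 counts in its place. Log2 ratios are aged over young, from UMIs summed over the cells of a class. Of the 106 list medians compared, 75 lay outside the central 95% of 10000 random lists matched on expression. A median printed below that lay inside it is said to lie within random lists. Cell classes are named from clusters and are called T-like, B-like and so on.

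The first comparison asked which leukocyte classes differed in share between the ages. B-like cells made up a larger share of the aged than of the young library in 3 tissues. In the peritoneal cavity they were 44.3% of young and 64.8% of aged cells (ratio 1.46, 1.39 to 1.54), in the spleen 46.6% and 60.2% (ratio 1.29, 1.24 to 1.35), and in the lung 27.6% and 35.4% (ratio 1.28, 1.19 to 1.38). In the liver they were lower, at 37.4% and 25.8% (ratio 0.689, 0.620 to 0.768). Plasma-like cells, the antibody-secreting stage, were 0.330% of young and 1.26% of aged spleen cells (21 and 99 cells, ratio 3.81, 2.36 to 6.42). NK- or ILC1-like cells were lower with age in lung (15.4% and 5.63%, ratio 0.365, 0.315 to 0.422) and spleen (3.51% and 1.84%, ratio 0.525, 0.423 to 0.650). Macrophage-like cells were lower in lung (11.7%, 10.9 to 12.6, and 4.18%, 3.59 to 4.83) and peritoneal cavity (38.8% and 13.1%, ratio 0.339, 0.311 to 0.368).

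Granulocyte and dendritic classes differed as well. Neutrophil-like cells were higher in the aged lung (10.8% and 22.5%, ratio 2.08, 1.88 to 2.31) and liver (4.73% and 9.55%, ratio 2.02, 1.55 to 2.66). In the spleen the neutrophil ratio was 1.15 (0.867 to 1.53). Conventional dendritic cell 1-like cells, which cross-present antigen, were higher in liver (ratio 2.02, 1.27 to 3.34) and spleen (ratio 1.93, 1.27 to 3.00), where the ratio without doublet removal was 1.42 (0.977 to 2.08). Plasmacytoid dendritic-like cells, known for type I interferon, were lower in liver (5.36% and 1.74%, ratio 0.324, 0.229 to 0.456). Monocyte-like cells were 3.11% and 11.5% of liver cells (ratio 3.71, 2.72 to 5.18), and their lung ratio was 1.69. With all barcodes, without doublet removal and with another random start the class kept 4, 3 and 3 young and 13, 6 and 7 aged liver cells, with ratios of 1.23, 0.728 and 0.870, and at most 9 young and 3 aged lung cells. Both shares thus depended on whether the large clusters took the monocyte name, and no direction is given for them. The young liver library was the smallest and held 11.4% endothelial-like cells, which lack CD45, against 2.21% in the aged one. The mitochondrial limit removed 18.3% and 14.1% of aged and young spleen barcodes, 10.9% and 9.01% of the peritoneal ones, and 2.53% to 5.35% of the lung and liver ones. Unnamed clusters held 11.2% of young and 19.1% of aged liver cells, 8.55% and 14.0% in lung, 5.33% and 5.59% in peritoneal cavity and 5.55% and 7.01% in spleen.

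**Figure D1:**
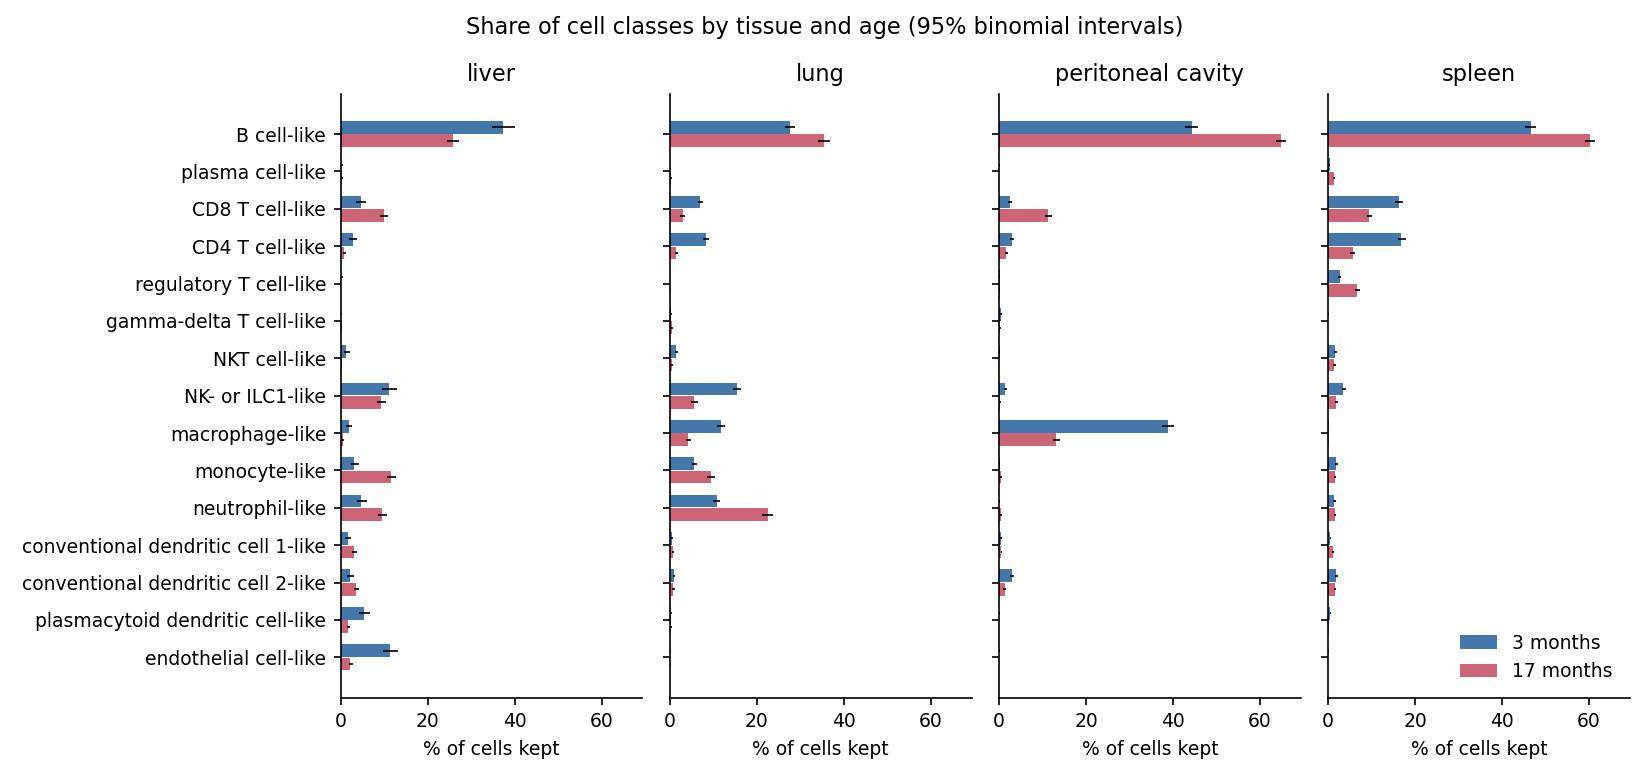
Percent of kept cells in each cell class (horizontal axis) for the young and aged library of each tissue, with exact 95% binomial intervals. CD8 T-like cells were 2.58% of young and 11.3% of aged peritoneal cells, and macrophage-like cells 38.8% and 13.1%.

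The next comparison asked how the CD8 and CD4 T cell compartments differed. CD8 T-like cells, the killer lineage, were a larger share of the aged liver and peritoneal cavity and a smaller share of the aged lung and spleen. In the liver they were 4.59% (3.56 to 5.81) of young and 9.89% (8.96 to 10.9) of aged cells, from 65 and 376 cells. In the peritoneal cavity they were 2.58% (2.16 to 3.07) and 11.3% (10.5 to 12.1), from 125 and 678 cells. In the lung they were 6.98% (6.34 to 7.65) and 2.90% (2.41 to 3.46), and in the spleen 16.2% (15.3 to 17.2) and 9.49% (8.86 to 10.2). Of the cells in CD3 clusters they were 35.3% (28.4 to 42.7) of young and 42.4% (39.1 to 45.7) of aged cells in liver, with overlapping intervals, 29.9% and 18.5% in lung, 24.9% and 62.5% in peritoneal cavity and 39.4% and 34.3% in spleen. CD4 T-like cells, the helper lineage, had ratios below 1 as clustered, at 0.306 in liver, 0.178 in lung, 0.563 in peritoneal cavity and 0.334 in spleen. Regulatory T-like cells, marked by Foxp3, were higher in the spleen, at 2.63% and 6.68% of all cells (ratio 2.54, 2.13 to 3.04) and 6.38% and 24.1% of cells in CD3 clusters.

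Different clusters held most of the liver CD8 T-like cells at each age, and in the other tissues the mix of CD8 clusters shifted. Cluster T:5 held 55 of the 65 young liver CD8 T-like cells, and cluster T:9 held 304 of the 376 aged ones but 2 young ones, and a cluster held mostly by 1 library can stand for that library. In the peritoneal cavity T:15 and T:12 held 49 and 40 young cells, and T:12, T:6 and T:15 held 229, 210 and 188 aged cells. In the spleen T:1 held 750 young and 261 aged cells, and T:6 held 217 aged cells. In the lung T:5 held 364 young and 72 aged cells, and T:9 held 1 (0.242%) and 35 (29.2%). CD4 T-like cells of liver and lung were in T:3 at both ages (98.4% to 100%), and the spleen clusters were T:0 (987 and 296 cells) and T:7 (85 and 147 cells). Clusters with CD8 UMIs but led by NK markers stayed outside the class and held 2.68% of young and 8.37% of aged liver cells, 3.88% and 5.41% in lung, 0.661% and 0.350% in peritoneal cavity and 1.73% and 1.49% in spleen. Clusters kept out of the CD4 class held 0.267% and 2.01% of spleen, 3.10% and 3.10% of peritoneal, 0.996% and 1.28% of lung and 0.212% and 1.08% of liver cells. Counting single cells by Cd3, Cd8 and Cd4 UMIs gave the same directions for CD8, but the lung ratio was 0.870 (0.755 to 1.00) in place of 0.415, and the CD4 ratios were nearer 1, at 0.959 (0.569 to 1.67) in liver, 0.385 in lung, 0.773 (0.604 to 0.987) in peritoneal cavity and 0.596 in spleen.

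Gzmk encodes granzyme K, a granule protease of some memory CD8 T cells (ENSMUSG00000042385, GRCm38 chromosome 13, 113171608 to 113225908). The question, for which this series is known, was whether aged CD8 T-like cells carried it more often. After thinning to 1000 UMIs, 3.12% (0.381 to 10.8, 2 of 64 cells) of young and 49.2% (43.9 to 54.4, 179 of 364) of aged liver cells had a Gzmk UMI. The lung gave 0 of 394 young cells, which allows up to 0.761%, and 21.8% (14.5 to 30.7) of 110 aged cells. The peritoneal cavity gave 5.65% (2.30 to 11.3) of 124 and 18.2% (15.3 to 21.3) of 666 cells. The spleen gave 0.593% (0.218 to 1.29) of 1012 and 20.8% (17.9 to 23.9) of 735 cells. Without thinning the young and aged shares were 3.08% and 72.1%, 0.242% and 27.5%, 9.60% and 29.2%, and 1.16% and 30.2%, in the same order of tissues. In B-like cells of the same libraries, thinned alike, at most 0.134% had a Gzmk UMI. The CD8 shares depended on which cells took the CD8 name. With the NK-led clusters counted as CD8, the 8 shares ran from 0.715% to 34.9%, so the young lung share was no longer 0. With single-cell gates they ran from 0.545% to 36.1%. The aged liver share was thus below the 49.2% given above in both settings.

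By summed UMIs the Gzmk log2 ratio was 5.56 (4.36 to 7.61) in liver, 7.58 (6.02 to 10.96) in lung, 2.33 (1.80 to 2.97) in peritoneal cavity and 5.80 (5.26 to 6.46) in spleen. The lung ratio rested on 2 young UMIs and 150 aged ones. It was 3.14 with cells picked by single-cell UMIs, and the spleen ratio was 2.12 when each tissue was clustered on its own. In the peritoneal library Gzmk was also higher in other classes, with 2.65 (1.57 to 4.05) in CD4 T-like and 5.03 (3.96 to 6.62) in macrophage-like cells, and 45 aged against 0 young UMIs in B-like cells. Its aged level there was 115, 11.7 and 2.60 CPM, against 260 CPM in CD8 T-like cells. It was also higher in spleen CD4 T-like cells (3.40, 2.38 to 4.69, from 9 and 37 UMIs) and lung NK- or ILC1-like cells (1.86, 0.47 to 3.33, from 9 and 11 UMIs), with 0 young and 10 aged UMIs in lung monocyte-like cells, and lower in liver NK- or ILC1-like cells (−3.02, from 10 and 2 UMIs). The aged levels of these 4 were 23.5, 13.7, 3.36 and 1.65 CPM. Thinning left out 1 young and 12 aged liver cells, 19 and 10 lung cells, 1 and 12 peritoneal cells and 20 and 13 spleen cells. Median depths of young and aged CD8 T-like cells were 4471 and 3008 UMIs in liver, 3897 and 4077 in lung, 4051 and 3795.5 in peritoneal cavity and 4638.5 and 4654 in spleen. Those of B-like cells were 2729 and 2088.5, 2341.5 and 2624, 4669.5 and 3272, and 2920 and 2610.

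**Figure D2:**
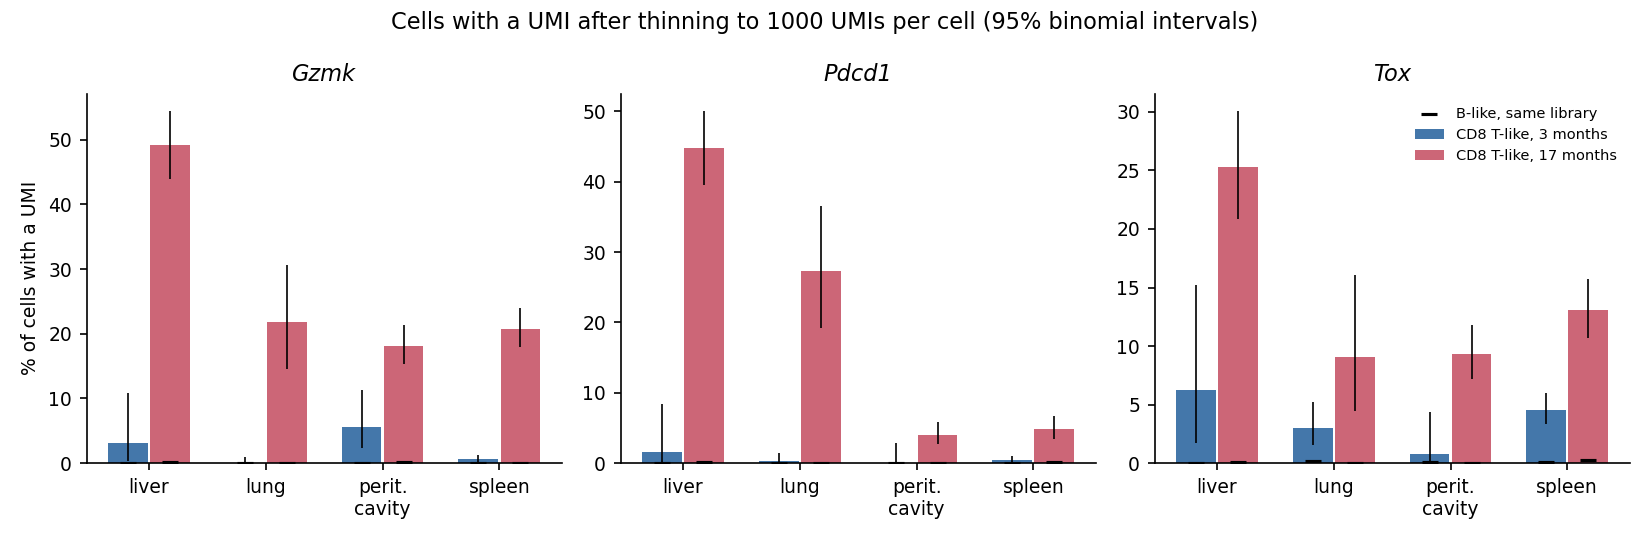
Percent of CD8 T-like cells with a UMI of Gzmk, Pdcd1 or Tox (vertical axis) in each tissue and age after thinning to 1000 UMIs per cell, with exact 95% binomial intervals and a dash for B-like cells of the same library. Gzmk stood at 0% to 5.65% in the 4 young and at 18.2% to 49.2% in the 4 aged libraries.

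Beyond Gzmk, the lists of inhibitory receptor, effector and S100 genes had medians above 0 in aged CD8 T-like cells of all 4 tissues, lowest in the peritoneal cavity. The list of inhibitory receptors and the TOX programme, which marks chronically stimulated T cells, had medians of 3.82 in liver (11 of 11 measured members at least 1.5-fold higher), 2.61 in lung (8 of 8), 1.19 in peritoneal cavity (7 of 8) and 1.56 in spleen (9 of 10), at percentiles of 99.99 or above. Pdcd1, the receptor PD-1 (ENSMUSG00000026285, chromosome 1, 94038305 to 94052553), had log2 ratios of 5.11, 5.37, 2.17 and 3.38 in liver, lung, peritoneal cavity and spleen. Tox, a transcription factor of exhausted T cells (ENSMUSG00000041272, chromosome 4, 6686353 to 6991557), had 2.33, 1.67, 1.79 and 1.14 in the same order. Tigit had 3.58, 2.61, 1.17 and 4.45. In peritoneal cavity Tigit, and in spleen Pdcd1 and Ccl4, were higher in all 3 classes that measured them, so these values are not particular to CD8 T-like cells. Lag3 had 5.49 in lung and 4.49 in spleen, and in liver 246 aged UMIs against 0 young ones, at least 4.29 log2 units higher against a floor of 3 counts over the group. The cytotoxic and effector list had medians of 2.89, 4.06, 0.73 and 2.52, with 12 of 14, 9 of 10, 8 of 14 and 17 of 18 members at least 1.5-fold higher. Gzmb, a killing protease (ENSMUSG00000015437, chromosome 14, 56258838 to 56262260), had 6.06 (4.52 to 9.43) in liver and 6.80 (5.22 to 10.18) in lung, from 2 young UMIs each, and 3.22 in spleen. The chemokine gene Ccl5 (ENSMUSG00000035042, chromosome 11, 83525778 to 83530518) had 4.12, 5.16, 0.27 and 3.14, and Ccl4 3.64, 2.00 and 5.25 in lung, peritoneal cavity and spleen.

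Homing and memory genes went the other way mainly in the liver. The naive and central memory list had a median of −2.23 in liver, where all 14 members were at least 1.5-fold lower, and −0.28 in lung, 0.19 in peritoneal cavity (within random lists) and −0.30 in spleen. Ccr7, a lymph node homing receptor, had −2.32, −0.19, 0.19 and −0.62, and Tcf7 −1.97, −0.69, 0.07 and −0.35. Tissue residency genes had medians of 3.73, 1.24, 0.77 and 0.56, with 5 of 6, 3 of 6, 3 of 5 and 4 of 8 members at least 1.5-fold higher. Among them Cxcr6 had 4.79 (3.25 to 8.16, from 2 young UMIs), 2.17, 1.43 and 0.44, while Itgae was −0.90 in lung and −1.15 in spleen. With the members that had 0 young UMIs set at their bound from a floor of 3 counts, the liver medians were 3.58 for the inhibitory, 2.61 for the cytotoxic and 2.79 for the residency list.

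Part of the CD8 list of named genes was held by calcium-binding and antigen presentation genes. S100a6 (ENSMUSG00000001025, chromosome 3, 90612882 to 90624181) had 5.89, 4.70, 0.81 and 3.68, and the list of S100, annexin and galectin genes had medians of 1.81, 1.06, 0.21 and 1.07, with 8 of 10, 7 of 10, 4 of 10 and 9 of 11 members at least 1.5-fold higher. The stress gene Ier3 had 5.50 (3.59 to 11.39, from 1 young UMI) in liver, 1.77 in peritoneal cavity and 2.62 in spleen. It was, with Gzmk, Pdcd1, Tox and S100a6, among the 5 genes at least 1.5-fold higher in all 4 tissues by the interval bound nearest 0, and no gene was lower by that rule. Maf, a transcription factor, had 6.32 (4.42 to 12.21), 4.06, 2.08 (0.47 to 5.47) and 3.86, with 1 and 2 young UMIs in liver and peritoneal cavity (ENSMUSG00000055435, chromosome 8, 115682942 to 115707794). MHC class I pathway genes had medians of 0.92, 0.32, 0.22 and 0.33, and proliferation genes −0.37, −0.31, 0.15 (within random lists) and 0.72. The proliferation medians rested on 4, 3, 4 and 6 members. The lung value had a counting interval of −0.69 to 0.49 and changed to 0.49 with the stricter filter and 0.38 at resolution 0.8. With the stricter filter and the third random start, a T cell cluster led by cycling genes stayed outside the CD8 class. These medians may therefore miss cycling CD8 cells. Cd74, a B cell and myeloid gene, had 1.66, 1.19, 1.75 and 1.96, and its share of CD8 T-like cells was 28.6% and 73.4% in spleen and 33.6% and 67.8% in peritoneal cavity. Named lower genes were Dapl1 (−2.97) and Rgcc (−2.60) in liver, Cox6a1 (−2.77), Eif1 (−2.49) and Cox5b (−2.40) in peritoneal cavity, and Tprgl (−2.46), Arf5 (−2.29) and Rnf187 (−2.27) in spleen. Of these, Cox6a1, Eif1, Cox5b and Arf5 were lower in every class of their library that measured them. In liver CD8 T-like cells the median of all genes was itself 0.26 and became −0.01 when immunoglobulin, mitochondrial and ribosomal genes left the totals, and in lung it was 0.12 and became −0.06 with size factors.

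The share of single cells with Pdcd1 or Tox was also higher. After thinning, 1.56% of young and 44.8% of aged liver CD8 T-like cells had a Pdcd1 UMI (3.08% and 67.3% unthinned), 0.254% and 27.3% in lung (1.94% and 29.2%), 0 of 124 cells (up to 2.42%) and 4.05% in peritoneal cavity (3.20% and 10.0%), and 0.395% and 4.90% in spleen (1.36% and 11.6%). Tox stood at 6.25% and 25.3% in liver, 3.05% and 9.09% in lung, 0.806% and 9.31% in peritoneal cavity and 4.55% and 13.1% in spleen, with at most 0.292% of B-like cells. Unthinned, these were 16.9% and 49.7%, 10.2% and 23.3%, 8.80% and 19.8%, and 18.8% and 29.9%.

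**Figure D3:**
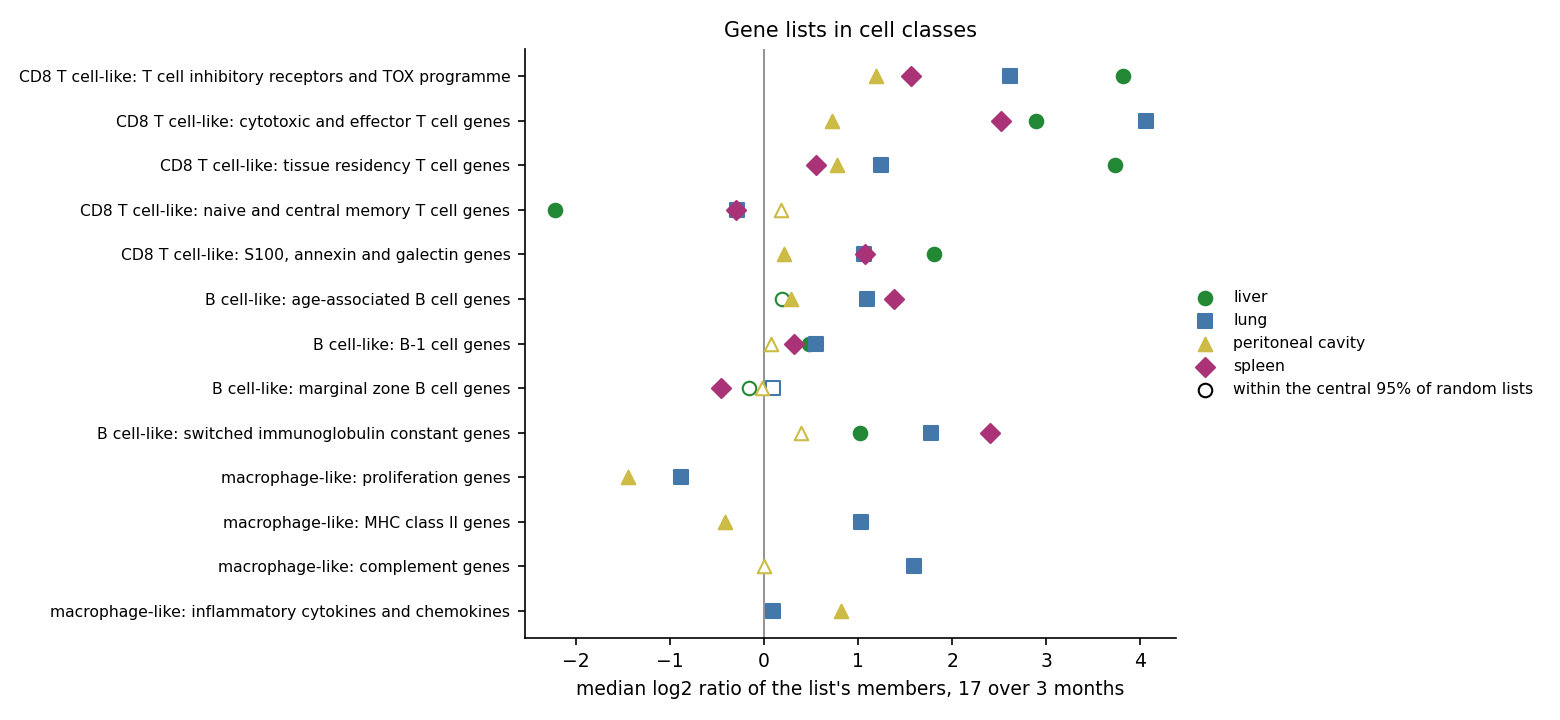
Median log2 ratio, aged over young, of gene lists in CD8 T-, B- and macrophage-like cells (horizontal axis), with 1 symbol per tissue that is filled where the median lay outside the central 95% of random lists. The inhibitory receptor list in CD8 T-like cells ran from 1.19 in peritoneal cavity to 3.82 in liver; under the scaling alternatives the B-1 and switched immunoglobulin lists in peritoneal B-like cells, the marginal zone list in lung B-like cells and the complement list in peritoneal macrophage-like cells changed sign, and the complement list in lung macrophage-like cells changed sign in the main cluster alone.

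In CD4 T-like cells the comparison asked whether helper cells carried the same receptors. In the spleen the inhibitory list had a median of 1.71 with 5 of 6 members at least 1.5-fold higher, and Tigit had a log2 ratio of 2.91. The follicular helper list, genes of T cells that help germinal centre B cells, had 1.65 in spleen and 0.75 in peritoneal cavity. The S100 list had 0.89 in spleen. Its medians of 0.10 in peritoneal cavity and −0.15 in lung, and that of helper cytokines of 0.26 in spleen, lay within random lists. The inhibitory list had 0.73 in lung and 0.91 in peritoneal cavity, from 4 members each. With cells picked by Cd3 and Cd4 UMIs, which keep regulatory T cells, it had 2.14 in lung and 1.79 in peritoneal cavity. There 7 of 7 and 4 of 4 members were at least 1.5-fold higher. Genes of other cells differed in the same gated cells. In lung MHC class II genes had 4.63 and the regulatory list 1.73, from 69 aged cells. In peritoneal cavity macrophage residency genes had 2.16 and complement genes 2.21, while MHC class II genes had −2.18 and the regulatory list −0.02. The gated medians are therefore not assigned to helper cells alone. The naive list had −0.30 in spleen, and 0.13 in lung, which lay within random lists and where size factors gave −0.03. It was −0.55 in lung with cells picked by Cd3 and Cd4 UMIs. In peritoneal cavity it had 0.53, which turned to −0.09 with cells picked by Cd3 and Cd4 UMIs. Named genes included Ccl5 (1.84), Cd74 (2.27), Pcbp2 (−1.99) and Rac1 (−1.98) in spleen and Eif1 (−2.53) and Cox5b (−2.82) in peritoneal cavity, the 4 latter lower in every class of their library that measured them.

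Because clusters kept out of the CD4 class held 2.01% of aged spleen cells, spleen cells with Cd3 and Cd4 UMIs and no Cd8 or B cell UMIs were also compared (596 young and 440 aged cells). Among these, Pdcd1 was seen in 2.87% (1.68 to 4.56) of young and 15.9% (12.6 to 19.7) of aged cells after thinning. Il21, the cytokine of follicular helper cells, was seen in 0 of 592 young cells, which allows up to 0.507%, and in 3.46% of 434 aged ones. Sostdc1, a follicular T cell gene (ENSMUSG00000036169, chromosome 12, 36314139 to 36318452), was seen in 0.845% and 9.22%. Unthinned shares were 6.71% and 31.1% for Pdcd1, 0.336% and 7.27% for Il21 and 1.01% and 12.3% for Sostdc1. At most 0.157% of B-like cells had Pdcd1, Il21 or Sostdc1. Median depths were 4107 and 3081.5 UMIs, with 4 and 6 cells left out. The follicular helper list had a median of 2.79 (9 of 9 members at least 1.5-fold higher), the inhibitory list 2.38 and the naive list −1.10. The gate kept regulatory T cells, and their list had 1.77 (9 of 12 members at least 1.5-fold higher), so these medians are not assigned to helper cells alone. The MHC class II list, B cell genes, had 2.01 in the same cells.

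Regulatory T-like cells of the spleen were compared for their resting and suppressive genes. The naive list had a median of −1.29, with 11 of 14 members at least 1.5-fold lower, among them Satb1 (−2.24), Bach2 (−2.25) and Klf2 (−1.63), while Tcf7 had 0.45. The regulatory list had 0.30 at percentile 95.5, within random lists, with Foxp3 at −0.26, Il2ra, the interleukin 2 receptor alpha chain, at −1.67 and Izumo1r at 0.81. The inhibitory list had 0.76, with Lag3 at 1.86, Tigit at 1.34 and Pdcd1 at 1.01. Named genes of this class were Igkc (3.43) and Jchain (3.73, 2.14 to 7.11, from 2 young UMIs), made by B and plasma cells, and the lower Tmem160 (−3.57), Bri3 (−3.55) and Tesc (−3.51). The class was a single cluster, T:2, with 167 young and 526 aged spleen cells. With the third random start the class held 151 and 409 spleen cells. There an unnamed cluster led by Sostdc1 and Izumo1r held 44 and 315. Some aged cells of T:2 may therefore be follicular-like CD4 cells, and these values are not assigned to regulatory T cells alone.

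B-like cells were compared for the age-associated, innate-like and class-switched states. The age-associated B cell list had a median of 1.38 in spleen (9 of 13 members at least 1.5-fold higher), 1.09 in lung (6 of 10), 0.28 in peritoneal cavity (5 of 12) and 0.20 in liver (3 of 7, within random lists). Tbx21, the T-bet gene (ENSMUSG00000001444, chromosome 11, 97098071 to 97115331), had 2.22 in spleen, 2.30 in lung and 0.46 in peritoneal cavity. Itgax, the CD11c gene, had 2.10 in spleen, and Zbtb32 had 1.67 in spleen and 1.95 in lung. Nt5e, the CD73 gene, had 2.88 (1.17 to 6.30, from 2 young UMIs), 2.16, 0.90 and 1.60 in liver, lung, peritoneal cavity and spleen. Switched immunoglobulin constant genes had medians of 1.02, 1.77, 0.39 and 2.41, and the peritoneal value lay within random lists and was −0.23 when every cell weighed the same. Ighg1 had 3.92, Ighg3 3.74 and Ighg2c 2.24 in spleen. Ighg3 and Ighg2b were higher in every spleen class that measured them, with Ighg3 at 6.21 (4.22 to 12.11, from 1 young UMI) in CD4 T-like cells, so free RNA may make up part of the rise of these genes in spleen B-like cells. Aged Ighg3 levels were 116 CPM in B-like, 26.1 in CD4 T-like and 19.0 in CD8 T-like cells. Igha (ENSMUSG00000095079, chromosome 12, 113254830 to 113260236) had 6.17 in liver, from 6 young and 646 aged UMIs. The S100 list had medians of 0.55, 0.35, 0.40 and 0.24.

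Other B cell lists varied between tissues. Marginal zone genes had −0.46 in spleen at percentile 0.02, with Marcks at −0.76, Cd1d1 at −0.65 and S1pr3 at −0.64, and −0.16, 0.09 and −0.02 in liver, lung and peritoneal cavity, all within random lists. B-1 cell genes had 0.48, 0.55, 0.08 (within random lists) and 0.31. Interferon-stimulated genes had −0.23, −0.11 and 0.12, within random lists, and −0.22 in spleen. Immediate early and heat shock genes had 0.51 in peritoneal cavity, with Jun at 1.75 and Nr4a1 at 1.80, and −0.13 (within random lists), 0.18 and −0.13 in liver, lung and spleen. Proliferation genes had 1.28 in peritoneal cavity and 0.44 in spleen. Their medians of 1.02 in liver and 1.14 in lung turned to −0.08 and −0.24 with the stricter cell filter. Under that filter a cluster led by cycling genes such as Mki67 stayed unnamed, while a like cluster was B-like with the third random start. The turns can therefore not be assigned to the filter alone. The unnamed cluster held 3 young and 4 aged liver, 1 and 4 lung, 3 and 19 peritoneal and 52 and 75 spleen cells. How far such cells make up the peritoneal 1.28 was not measured. The marginal zone value in lung and the B-1 value in peritoneal cavity changed to −0.04 and −0.12 when every cell weighed the same.

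Named B cell genes included Jchain, the joining chain of secreted antibody (ENSMUSG00000067149, chromosome 5, 88519809 to 88527891), at 5.98 (4.64 to 8.48) in liver and 8.85 (6.95 to 14.74) in lung, from 3 and 1 young UMIs, and 0.47 and 0.72 in peritoneal cavity and spleen. Without thinning it was seen in 0.0612% of young and 0.546% of aged lung B-like cells. Ccl5 had 3.13, −0.47, 2.81 and 2.48, Socs3 1.07, 1.47, 2.25 and 0.58, and the transcript AC133103.1 2.56, 2.51, 2.67 and 4.05. Lower ones were Glrx5 (−3.26 in liver, −3.80 in spleen), Bri3 (−2.33 and −3.87), Tprgl (−1.69 and −2.16) and, in peritoneal cavity, Fdx1l (−4.07), Mrpl54 (−3.36) and Hint2 (−2.89). In every peritoneal class that measured them Mrpl54 was lower and AC133103.1 higher, so these 2 values are not particular to B-like cells. Cluster 0 held 1779 young and 3088 aged spleen B-like cells and cluster 22 held 16 and 362. In peritoneal cavity cluster 4 held 1138 young cells and clusters 2 and 9 held 1659 and 981 aged ones. A cluster kept out of the class held 6.07% and 3.84% of young and aged liver cells and 1.20% and 1.62% of spleen cells.

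Receptor V genes were counted from the same UMIs. Among CD8 T-like cells of the liver with 1 Trbv gene, the effective number of Trbv genes was 15.4 in 46 young cells and 9.20 in 46 cells drawn from 260 aged ones. Trbv4 took 27.3% (21.99 to 33.15) and Trbv13-3 14.2% of the aged liver cells. The numbers were 15.3 and 16.5 in lung, 15.1 and 15.9 in peritoneal cavity and 17.6 and 17.4 in spleen. In peritoneal B-like cells Ighv11-2, a heavy chain segment common in B-1 cells, took 9.20% (7.75 to 10.8) of young and 18.0% (16.4 to 19.6) of aged cells with 1 Ighv gene. These were 1424 of 2142 young and 2268 of 3885 aged B-like cells. Free immunoglobulin RNA can change which cells have 1 Ighv gene, and its effect on these shares was not tested. The counts could not be split among the 3 pooled mice.

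NK- or ILC1-like cells were compared for cytotoxic genes. The cytotoxic list had medians of −0.38 in liver and, within random lists, −0.08 in lung and −0.23 in spleen. Gzmb had −1.28 in liver and −2.02 in spleen, Gzma −1.05 and −1.41, and Ifng −1.47 in liver. Kit, a receptor of immature and helper-like innate cells, had 2.01, 1.22 and 1.80 in liver, lung and spleen, and the surface glycoprotein gene Emb 1.24 and 1.16 in liver and lung. Immediate early and heat shock genes had −0.60 in liver, with Hspa1a at −2.03 and Hspa1b at −2.44, and −0.02 in lung and −0.19 in spleen, both within random lists. Hspa1a and Hspa1b were lower in every liver class that measured them. T cell genes moved in the class as well, with Cd3g at −4.08 in liver and 2.36 in spleen. Clusters 8 and 32 held most of the liver cells, and the median of all genes in liver was −0.12 and became 0.01 with size factors. Tmem160 (−4.28) and Bri3 (−3.91) were the lowest named genes in spleen. Cd74 (1.89) and H2-Aa (1.98) in lung turned to −0.49 and −0.75 without doublet removal.

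Macrophage-like cells, mainly cluster 14 in lung and cluster 3 in peritoneal cavity, were compared for cycling, antigen presentation and inflammatory genes. Proliferation genes were lower in both tissues, with medians of −0.88 in lung (9 of 12 members at least 1.5-fold lower) and −1.45 in peritoneal cavity (11 of 12). Mki67, present in cycling cells (ENSMUSG00000031004, chromosome 7, 135689784 to 135716361), had −1.09 and −1.44, Stmn1 −0.81 and −1.83, Ube2c −2.32 and −1.54, and Cenpe −2.21 (−5.61 to −0.59, from 2 aged UMIs) and −1.15. Many of these UMIs came from small clusters, and in the main cluster alone the medians were −0.45 and −0.21, while Ube2c had 0.91 in lung, from 5 young and 2 aged UMIs. Cluster 51 held 61.5% of young and 44.0% of aged Mki67 UMIs in lung, and cluster 35 held 93.0% and 85.0% in peritoneal cavity. Complement genes had a median of 1.59 in lung, with C1qa (ENSMUSG00000036887, chromosome 4, 136895917 to 136898803) at 1.66 and C1qc at 2.07. Cluster 47, with 6 young and 5 aged lung cells (0.863% and 2.89% of the class), held 74.6% of young and 100% of aged C1qa UMIs, and in cluster 14 alone the complement median was −1.19, so no direction is given for complement genes in lung. In peritoneal cavity the complement median was 0.00, within random lists. MHC class II genes had 1.03 in lung (1.01 in cluster 14 alone) and −0.42 in peritoneal cavity, which turned to 0.64 in cluster 3 alone. Inflammatory cytokines and chemokines had 0.09 in lung and 0.82 in peritoneal cavity, with Cxcl10 at 3.34 and Il1b at 0.85 in the latter.

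Single macrophage genes differed more. Apoe had 2.45 in lung and −0.18 in peritoneal cavity, Pf4 2.67 and −0.19, and Folr2 2.76 and 0.60, and the 5 aged lung cells of cluster 47 held 84.0%, 90.3% and 100% of the aged lung UMIs of these genes. Spp1, osteopontin, had 0.91 and 2.09, Ccl2 1.48 and 1.41, and Cd63 1.06 and 1.90. Peritoneal residency genes had a median of 0.21, with the B cell attractant Cxcl13 at 3.35 and the identity factor Gata6 at −0.07. Lipid handling genes had −0.02 and 0.00, both within random lists. Genes of other cells were also higher, with Thy1, a T cell gene, at 1.29 in lung and 2.29 in peritoneal cavity. S100a9, a neutrophil gene, had 1.35 and 9.91 (8.01 to 15.80), the latter from 1 young UMI, and Igkc was seen in 6.77% of young and 25.3% of aged peritoneal macrophage-like cells.

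Neutrophil-like cells were compared for granule and interferon genes. Camp, Ngp and Ltf, granule protein genes made before neutrophils leave the marrow, went in opposite directions between tissues. Camp had 632 aged and 0 young UMIs in liver, at least 5.62 log2 units higher by the same floor, 2.75 in lung, and 0 aged and 3649 young UMIs in spleen, at least 10.32 units lower. Ngp had 3.52, 1.15 and −8.77 in liver, lung and spleen, and Ltf was 2.56 (1.18 to 5.08, from 3 young UMIs) and 1.49 in liver and lung and at least 8.35 units lower in spleen. Inflammatory genes had medians of 0.09, −0.07 and 0.24, all within random lists, and the lung and spleen values changed to 0.08 and −0.09 when every cell weighed the same. Interferon-stimulated genes had 0.31 in lung, where members with at least 100 UMIs gave −0.04, and, within random lists, −0.36 in liver and 0.41 in spleen, the latter of which changed to −0.12 when every cell weighed the same. In the B-like cells of the same spleen libraries S100a8 and S100a9, abundant neutrophil transcripts, were also lower, at −5.64 and −6.18. The median of all genes was −0.15 in liver and 0.25 in spleen, and size factors made these −0.00 and 0.03. A cluster kept out of the class held 89 aged liver cells and 0 young ones.

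In monocyte-like cells 6 genes were higher and 1 lower beyond 1.5-fold in both compared tissues, by the interval bound nearest 0. Conventional dendritic cell 2-like cells had 3 and 1, against 17 and 2 in macrophage-like cells. In monocyte-like cells F13a1 had 0.76 in lung and 0.89 in spleen, and Fn1 0.70 and 0.78. B cell genes were also higher in these cells, with Cd79a at 2.67 and 2.17 and Ighm at 2.99 and 0.28 in lung and spleen, and Igkc at 5.63 in lung. In the 3 settings named above, which left at most 9 young and 3 aged lung cells in the class, several lung values turned, such as Cd79a to −3.18 from 10 young and 0 aged UMIs, and such counts neither support nor contradict them. Their inflammatory list had −0.14 and −0.30, the latter within random lists. Their MHC class II list had 0.28 and 0.26, which turned to −4.67 in lung without doublet removal, from 5 young cells and 1 aged cell, and to −0.14 in spleen with the stricter filter. In conventional dendritic cell 2-like cells, which prime CD4 T cells, Fabp5 had 1.87 in peritoneal cavity and 1.46 in spleen. Fscn1 had −4.39 (−10.29 to −2.41) in peritoneal cavity, from 1 aged and 49 young UMIs, and Clec10a 2.35 in spleen. Interferon-stimulated genes had 0.65 in peritoneal cavity and −0.42 in spleen, and MHC class II genes −0.16 and 0.09, the latter within random lists. In plasmacytoid dendritic-like cells of the liver the heat shock genes Hspa1b and Hspa1a, lower in the other liver classes as well, had −5.49 (−8.87 to −3.94) and −4.18.

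A last comparison looked for genes that moved alike across the classes of a library, among genes with at least 20 summed UMIs in 3 or more classes. In the spleen 84 of 9266 genes were at least 2-fold lower in every class that measured them, out of 9 classes, with a median log2 ratio of −1.91, and 10 genes, among them Pdcd1 and Ccl4, were higher. In the peritoneal cavity 38 of 8076 genes were lower in every class that measured them, out of 5, with a median of −1.72, and 10 genes, among them Gzmk, Tigit and Cxcl13, were higher. There were 8 such lower genes and 1 higher gene in liver, and 0 and 4 in lung. Of the lower liver genes, Iscu, Pcbd2, Smap1, Srm and Trim59 were also among those of the spleen. Bri3 (ENSMUSG00000047843, chromosome 5, 144244437 to 144446757) and Cox5b (ENSMUSG00000061518, chromosome 1, 36691449 to 36693681) are examples from the spleen and the peritoneal cavity. The first 300 nt of the spleen transcripts had a median GC content of 70.0%, against 58.7% for all compared genes. Immunoglobulin RNA was also more widespread in the aged spleen. Without thinning, Igkc was seen in 8.91% of young and 47.1% of aged CD8 T-like cells, 8.12% and 41.3% of CD4 T-like, 11.7% and 38.6% of NK- or ILC1-like and 9.20% and 43.5% of neutrophil-like cells, beside 90.0% and 90.3% of B-like cells.

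**Figure D4:**
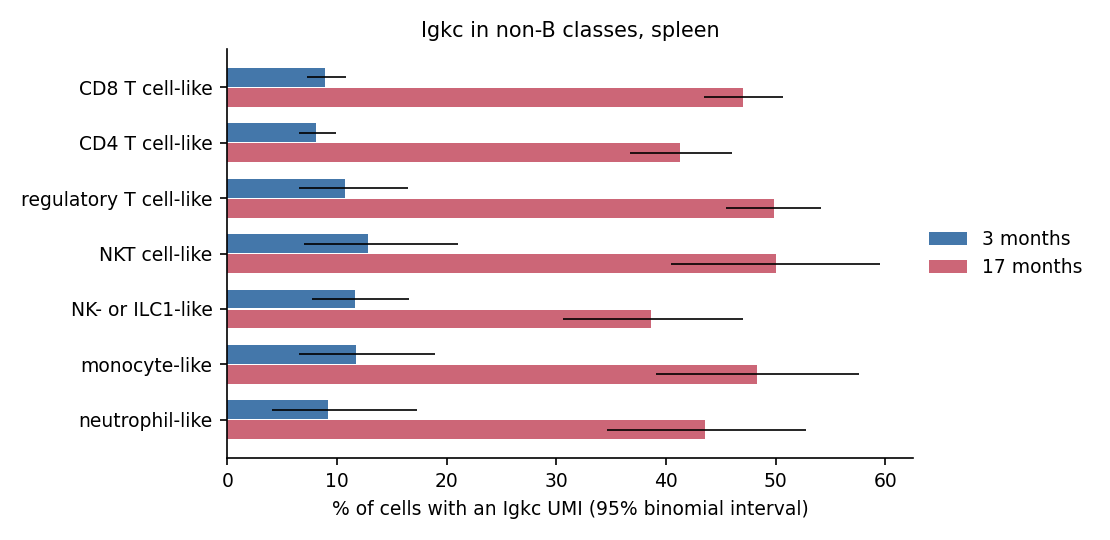
Percent of cells with an Igkc UMI (horizontal axis) in the non-B classes of the young and aged spleen libraries, with exact 95% binomial intervals. The 7 classes stood at 8.12% to 12.9% in the young and at 38.6% to 50.0% in the aged library.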

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

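All of the differences between tissues named here were noticed after the results were seen, and none of these differences was tested, since each tissue and age had 1 library. They are listed because, as clustered, the aged library stood above the young one in some tissues and below it in others, beyond counting error.

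The aged over young ratio of the CD8 T-like share was 2.16 in liver and 4.38 in peritoneal cavity, and 0.415 in lung and 0.585 in spleen. Counted by single-cell UMIs the lung ratio was 0.870 (0.755 to 1.00), which lay within counting error. In NK- or ILC1-like cells the T cell gene Cd3g had a log2 ratio of −4.08 in liver and 2.36 in spleen. In macrophage-like cells Timp1, an inhibitor of matrix proteases, had 5.38 in peritoneal cavity, from 4 young and 82 aged UMIs. In lung it had 71 young and 0 aged UMIs, a log2 ratio of −2.47 or below against the floor of 3 counts over the group.

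In neutrophil-like cells the granule gene Camp had log2 ratios of at least 5.62 in liver, 2.75 in lung and at most −10.32 in spleen, where the liver and spleen values are bounds from the same floor. Ngp had 3.52 in liver and −8.77 in spleen. Ltf had 2.56 in liver (1.18 to 5.08, from 3 young UMIs) and at most −8.35 in spleen.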

How the results depend on the processing

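The random starts, the NK-led clusters counted as CD8, the GC trend, the CD4 gate and the main macrophage cluster alone were chosen after the results were seen, and the other alternatives beforehand. No paired analysis was possible because each tissue and age had 1 library and the labels pair no mice. The log2 ratio of Gzmk stayed above 0 in all 60 alternative values, from 1.81 to 10.03, and 10 of them lay outside the counting interval. Of the 260 alternative values of class shares, 38 lay outside it and 2 turned direction. Of 1589 values of list medians 220 moved and 9 turned, of 2121 values of named genes 192 moved and 18 turned, and of 112 values of the Gzmk share 31 moved and 0 turned. The per-cell gates gave a value for 17 of the 27 class shares and for the lists of CD4 T-like cells alone, the minimum of 100 UMIs for 90 of 106 lists, and other filters and clusterings for 104 to 106. Each tissue clustered on its own was run for class shares and Gzmk alone. A turn was counted where the main counting interval excluded 0 and, for lists, the median also lay outside the central 95% of random lists. Among the other results 40 values of list medians and 3 of class shares changed sign. The effective Trbv number of aged liver CD8 T-like cells was 12.2 with gates, against 9.20.

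For class shares, the log2 ratio of the B-like share moved to −0.27 in liver at resolution 2.5 and to 0.94 in peritoneal cavity with gates. That of CD8 T-like cells in liver moved to 1.54 at resolution 0.8 and 1.67 with each tissue clustered on its own. In lung it moved to −0.50 with the stricter filter, −0.55 without doublet removal, −0.63 at resolution 0.8, −0.41 with each tissue on its own and −0.20 with gates. In peritoneal cavity it moved to 1.80 without doublet removal and 1.79 at resolution 0.8. In spleen it moved to −0.56 with the stricter filter, −1.03 at resolution 2.5, −1.23 with each tissue on its own and −1.17 with gates. The lung monocyte share turned to −1.08 with all barcodes and −1.78 without doublet removal. The class held 9 young and 3 aged lung cells in the first, 5 and 1 in the second and 4 and 3 with the third start, so its values under these 3 settings give no direction. They hold 13 of the 29 turns.

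The Gzmk log2 ratio moved to 3.75 in liver with gates. In lung it moved to 3.94 with the stricter filter, 4.45 without doublet removal, 4.07 at resolution 0.8, 3.76 with each tissue on its own, 3.14 with gates and 3.76 with the NK-led clusters. In spleen it moved to 4.99 at resolution 2.5, 2.12 with each tissue on its own and 4.71 with gates. The share of aged liver CD8 T-like cells with a Gzmk UMI was at most 34.9% with the NK-led clusters and at most 36.1% with gates. Both lay below its counting interval as clustered.

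Without doublet removal, NK- or ILC1-like cells of the lung turned to −0.49 for Cd74 and −0.75 for H2-Aa. Lung monocyte-like cells turned to −1.59 for Igkc, −3.18 for Cd79a, −2.69 for Ly6d, −0.66 for Cd79b, −0.66 for Ighm, 1.21 for Hpgd and −4.67 for MHC class II genes. Here Cd79b and Ighm had 5 young UMIs and 1 aged UMI each, and Hpgd had 0 at both ages. With the third random start, Igkc and Ly6d turned to −0.45, from 0 UMIs at both ages and thus from the group totals alone, and Hpgd to 1.87 from 0 and 2, and with all barcodes Ighm turned to −0.23. Apoe in peritoneal dendritic cell 2-like cells turned to 0.0770 with the stricter filter, 0.0833 with all barcodes, 0.0561 without doublet removal, 0.0698 at resolution 0.8 and 0.0698 with the third start. With the stricter filter, proliferation genes in B-like cells turned to −0.0759 in liver and −0.24 in lung, and MHC class II genes in spleen monocyte-like cells to −0.14, beside −0.0621 with all barcodes. The stricter filter also left a cluster led by cycling genes outside the B-like class. The naive list in peritoneal CD4 T-like cells turned to −0.0936 with gates, and interferon-stimulated genes in lung neutrophil-like cells to −0.0443 with members of at least 100 UMIs. With the main macrophage cluster alone, Ube2c in lung turned to 0.91, complement genes in lung to −1.19 and MHC class II genes in peritoneal cavity to 0.64.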

Other observations

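Among the aged libraries, the Gzmk-positive CD8 T-like cells differed from the Gzmk-negative ones in other genes too. After thinning, Ccl5 was seen in 100% of Gzmk-positive and 76.8% of Gzmk-negative cells in liver, 100% and 23.3% in lung, 97.52% and 63.1% in peritoneal cavity and 97.4% and 52.2% in spleen. Gzmb accompanied Gzmk in 39.7% of the positive cells in liver, 50.0% in lung and 11.8% in spleen, against 27.6%, 2.33% and 1.55% of the negative cells. In peritoneal cavity it was seen in 0 of 121 positive cells, which allows up to 2.48%, and in 1.47% of negative cells. Klrg1, a marker of short-lived effector cells, was seen in at most 2.48% of Gzmk-positive and at most 0.344% of Gzmk-negative cells.

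Genes outside the main lists also differed in rarer cells of the aged liver and spleen. Plasmacytoid dendritic-like cells of the aged liver had fewer UMIs of the early response gene Atf3, with a log2 ratio of −3.71 from 4 aged and 84 young UMIs. In spleen NK- or ILC1-like cells the chemokine gene Xcl1 had 2.02. In the aged spleen the effective number of Trbv genes of CD8 T-like cells was 17.4, close to the 17.6 of the young one.

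The comparisons in the opening paragraphs and the tests of free RNA, depth, a library difference, GC content and the Ighv11-2 partner in CD8 T-like cells were chosen after the result was seen, and the others before it. The first pattern is the higher Gzmk in aged CD8 T-like cells. Free RNA is argued against in CD8 T-like cells because at most 0.134% of B-like cells of the aged libraries had a Gzmk UMI. It stays open for the Gzmk UMIs of other classes of the aged peritoneal library, at 2.60 CPM in B-like and 11.7 CPM in macrophage-like cells against 260 CPM in CD8 T-like cells. There were 45 UMIs in 3885 B-like cells and 93 in 787 macrophage-like cells, less even per cell than a shared source gives. Free RNA alone is therefore not shown to be their source. Deeper cells are argued against because after thinning the aged interval lay above the young one in 4 of 4 tissues. Expanded clones of the most used Trbv4 and Trbv13-3 are argued against as the whole source, since 53.4% (46.3 to 60.4) of aged liver cells with other Trbv genes alone had Gzmk, against an upper bound of 10.8% for the young liver. What stays open is age itself, which was not tested apart from the library, since each age had 1 library per tissue, and a larger share of memory cells that express Gzmk at any age, which may also play a part and was not tested either.

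A linked hypothesis was that Gzmk-positive cells carry Pdcd1 or Tox more often in every aged library. The ratio of shares was 1.20 in liver (60.3% of positive and 50.3% of negative cells, with overlapping intervals), 9.56 in lung, 5.33 in peritoneal cavity and 4.97 in spleen. The liver therefore fell short of the 1.5 set beforehand, and the question stays undecided there.

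The second pattern is the 84 genes lower in every class of the aged spleen library that measured them. In spleen B-like cells the set kept a median log2 ratio of −1.82 after the GC trend was subtracted, and −2.08 with at most 5% mitochondrial UMIs, against −1.98 as counted. This argues against the general GC trend as the whole source and against damaged cells as seen by mitochondrial UMIs. The set was chosen for low values in these same cells, and the trend is that of all genes. A GC effect on part of the genes therefore stays open. A library difference not tied to age may account for the set, since its median level in B-like cells of the young peritoneal library was 7.04 CPM, below the 8.92 of the aged spleen. The young spleen, liver and lung stood at 41.5, 41.8 and 39.8 CPM and the aged peritoneal cavity at 5.34, so the low peritoneal level may also belong to that tissue. The same set had a median log2 ratio of −0.97 in liver, 0.07 in lung and −0.21 in peritoneal cavity. Age stays open as an untested explanation. Of the lower genes named for the spleen, Bri3, Tmem160, Glrx5, Arf5, Pcbp2, Rac1 and Tesc belong to this set, while Tprgl and Rnf187 do not.

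The third pattern is B cell RNA in every other class of the aged spleen. Free RNA in the droplets could account for it, since the highest mean of Igkc UMIs per cell over the non-B classes was 1.88 times the lowest, near the even spread that a shared source gives. Doublets with B cells are argued against, because CD8 T-like cells with Igkc exceeded those without it in Cd79a and Cd79b by 0.183% of the B-like level. Values of Igkc and Jchain in T, NK and myeloid classes of that library are therefore not read as expression by those cells. Age, with more plasma-like cells in the spleen, stays open as the reason for more free RNA and was not tested.

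In aged peritoneal B-like cells the kappa light chain segment known to pair with Ighv11-2 was seen in 99.5% of cells with Ighv11-2 and 22.6% of cells with another Ighv gene, a ratio of 4.41. It was also seen in 21.7% of CD8 T-like cells of that library, which do not make it, and 410 of the 420 other B-like cells had 1 or 2 UMIs. In the young library the shares were 96.9%, 2.78% and 2.40%. The ratio of 4.41 fell short of the fold set beforehand for this pairing of B-1 cells. That test stays undecided, because cells with 1 or 2 UMIs counted as positive. At least 10 UMIs of the segment were seen in 401 of 408 aged cells with Ighv11-2. They were seen in 4 of 1860 aged cells with another Ighv gene and in 0 of 678 aged CD8 T-like cells.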
